A study of Drosophila melanogaster with 9 samples.

How the data were processed

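Total RNA of Drosophila melanogaster embryo pools collected 4 to 8 h after egg laying was measured on Affymetrix 1-colour arrays, per the labels. The 9 arrays fall into 3 genotypes with 3 biological replicates each. w1118 is the control strain, Wwox1 a null allele made by homologous recombination, and Wwoxf04545 an allele with a pBac transposon insertion in exon 2. The group of each array was taken from the genotype label and the replicate number from the same sample's title. Each genotype carries the replicate numbers 1 to 3.

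The deposited values are a linear intensity per probe set. GCOS 1.4 is named in the submitters' processing notes. The summarisation method and the scaling target are not given in the sources used here. The mean after trimming 2% at each end was 100.003 on every array, so each array had been scaled by 1 factor. Medians and maxima differed between arrays, so the deposited intensity was not quantile-normalized. The design set beforehand called for quantile normalization only where a table was not yet normalized between arrays. The common trimmed mean was read as such a normalization, so the values were used as scaled, and quantile normalization was run as an alternative because the distributions still differed. No detection calls were used here, and the number of arrays limits the precision.

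The 183 control probe sets were left out, which left 18769 for testing. The platform annotation names 1 gene for 13647 of them, several genes for 402 and none for 4720. Called probe sets with no gene are described by their signal. Symbols were updated through the gene number in a RefSeq table of the assembly Release 6 plus ISO1 MT, which held 11894 of the 11983 genes with a probe set. That table was otherwise used only for the chromosome arm of a gene and for which genes neighbour each other, and none of its coordinates are given because no build is named for the array. No probe set carries the symbol w, the white gene, so it is not reported.

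Values were tested as log2(signal + 16) with limma 3.58.1 and statmod 1.5.0 in R 4.3.3. A single model with 1 mean per genotype was fitted to all 9 arrays, with 6 residual degrees of freedom, and 3 differences were tested: Wwox1 minus w1118, Wwoxf04545 minus w1118 and Wwox1 minus Wwoxf04545. P-values were adjusted by Benjamini-Hochberg within each difference, and a probe set or list is called where the adjusted p was under 0.05. Fold changes are on the log2(signal + 16) scale and understate the change of dim genes. Group values are mean signal ± SD of 3 arrays. The replicates are separate embryo pools, per the series' design text.

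The 27 gene lists were fixed before the data were examined. They were tested with camera, part of limma, on the brightest probe set of each gene and a preset correlation between genes of 0.01, and again with a correlation estimated from the arrays. Genes within 1 Mb of Wwox, Wwox left out, were compared with all other genes by Fisher's exact test, two-sided. The genes to be named were also set beforehand. For each allele against w1118 these were up to 12 called genes per direction, and up to 8 per direction for shared calls and for the difference between the alleles. A gene had to have a single symbol, a brighter group at or above the median of all probe set means, and groups that did not overlap. From each list, and from the genes near Wwox, up to 4 called members could be named, or the member with the smallest p where none was called. Wwox was always named. Other genes are named only with a statement that they were chosen after their values were seen.

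The replicate numbers were checked for pairing. Deviations from the genotype mean, over all probe sets, correlated at 0.146 to 0.439 in the 9 pairs of arrays that share a number, and at -0.396 to 0.331 in the 18 pairs that do not. All 9 pairs of the first kind lay above the limit of 0.1 set beforehand, so the numbers were taken to pair the pools across genotypes. Arrays numbered 1 that stand apart in every genotype also raise the correlations among the other arrays. Wwox1 replicate 2 correlated at 0.331 with w1118 replicate 3 and at 0.270 with w1118 replicate 2. The limit therefore cannot part pairing by each number from number 1 against the rest. The labels do not say what a number stands for. The planned model has no replicate block. The value with the block is given wherever it ended or made a call.

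The model was tested on simulated data for Wwox1 against w1118 over 18769 probe sets. It recovered 54.0% of probe sets changed by a log2 fold of 1, 82.2% at 1.5, 92.2% at 2 and 97.6% at 3, and 4.62% of its calls were false. Changes were placed only in probe sets at or above the median signal, 500 per size over 10 simulations. The noise was independent and had no replicate structure. So many changes ease the adjusted threshold, so recovery in the real comparison, with 4 calls, may be lower. The alternatives tried were the replicate block, quantile normalization, median centring, a filter on the dimmest 40% of probe sets, pseudocounts of 1 and 64, a variance trend, robust variances, array weights, only the 2 groups compared, a log2 fold of at least 1, an adjusted p under 0.01, each array left out, other list settings and windows of 0.25 and 5 Mb around Wwox. Leaving out the 3 arrays numbered 1 and quantile normalization together with the block were added after the data were seen. Figures were drawn with matplotlib 3.10.9 from the same result tables.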

Results

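Gene expression was measured in embryos of 2 Wwox mutant stocks and a control stock, 3 pools each. Wwox encodes a WW-domain oxidoreductase that lies at a chromosomal fragile site in humans, and the study asked which genes change when it is altered, with attention to aerobic metabolism and oxidative stress. Each array was scaled to a trimmed mean signal of 100.003. The median signal ran from 7.21 to 8.25 on 6 arrays and from 10.8 to 13.4 on the 3 arrays numbered 1. The highest signals were 6014 to 8576 and 12897 to 14941 in the same order. The 3 arrays numbered 1 also parted from the others on the first principal component, which held 37.8% of the variance, at -31.0 to -25.0 against 5.33 to 23.2.

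Wwox itself was low in both mutant stocks. Its signal was 121 ± 33.3 in w1118, 20.9 ± 1.55 in Wwox1 and 0.901 ± 0.544 in Wwoxf04545 (n = 3 each). The log2 fold change was -1.87 (SE 0.17, adjusted p = 0.0111, limma) in Wwox1 and -2.99 (SE 0.17, adjusted p = 0.000446) in Wwoxf04545. The 1.12 difference between the mutants was not called (adjusted p = 0.103). Where the probe set lies relative to the deletion or the insertion is not given in the sources used here, so the remaining Wwox1 signal is not a measure of intact transcript. The Wwox1 call was lost without any 1 of 5 arrays, at an adjusted p of 0.0674 without Wwox1 replicate 1, 0.113 without replicate 2, 0.122 without replicate 3, 0.0796 without w1118 replicate 2 and 0.0868 without w1118 replicate 3. For this dim signal the size of the change depended on the pseudocount: the Wwoxf04545 value was -6.01 with 1 and -1.50 with 64, at an adjusted p of 4.37e-07 to 0.0282 over all settings.

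**Figure D1:**
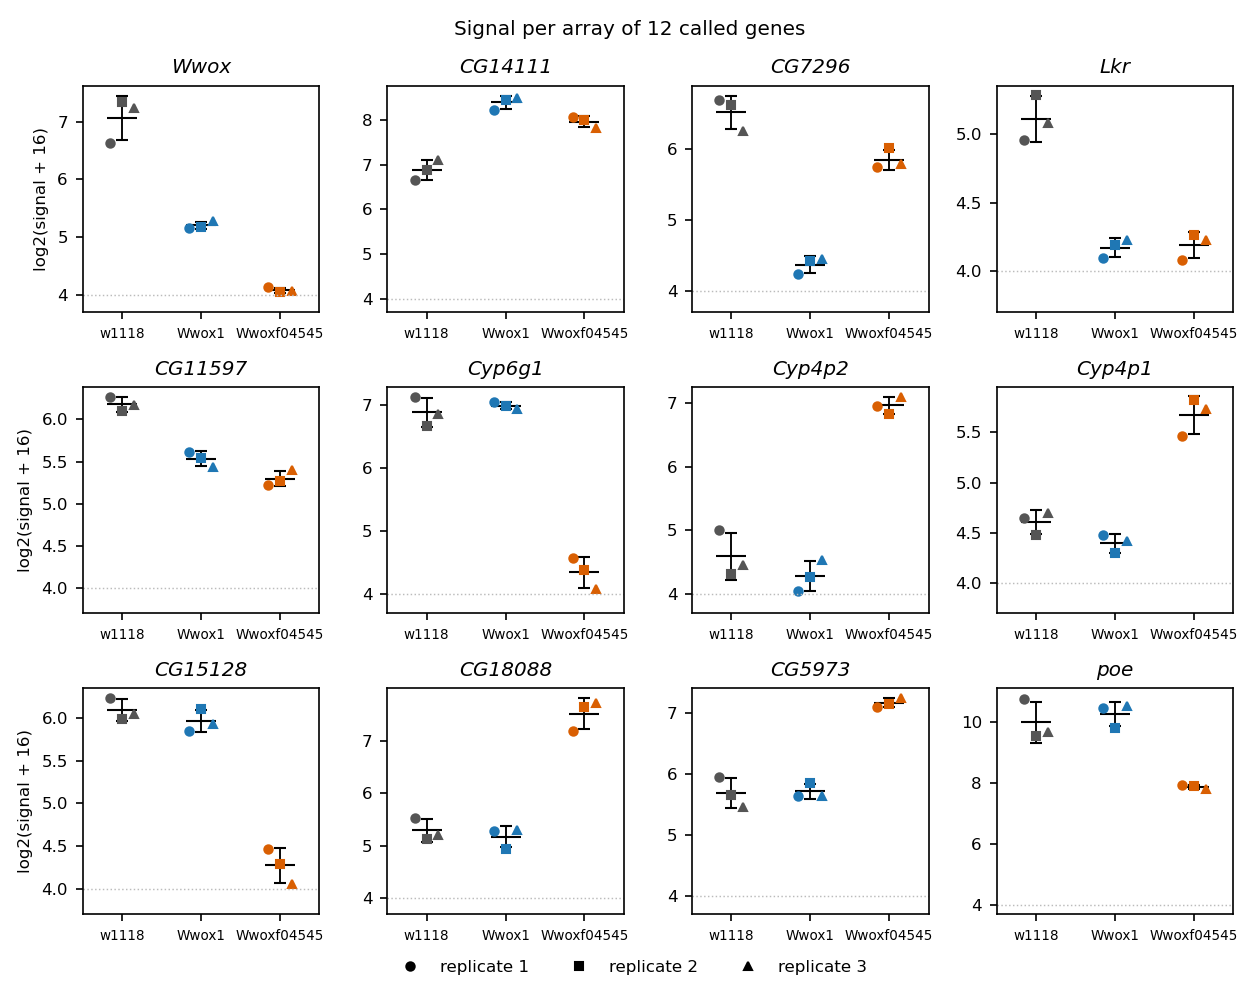
Signal of 12 called genes on each of the 9 arrays, as log2(signal + 16), by genotype; symbols mark the replicate number, bars the mean and SD of 3 arrays, and the dotted line a signal of 0. Wwox was lower in both mutants, CG14111 higher in both, and Cyp6g1, Cyp4p2, CG18088 and CG5973 set Wwoxf04545 apart from the other genotypes.

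In the null allele, 4 of 18769 probe sets were called against w1118, 1 higher and 3 lower. CG14111 rose from a signal of 103 ± 18.0 to 321 ± 32.3 (log2 fold change 1.51, SE 0.14, adjusted p = 0.0111). CG7296 fell from 76.1 ± 14.3 to 4.69 ± 1.67 (-2.15, SE 0.14, adjusted p = 0.00178). The remaining calls were Wwox and a probe set with no gene symbol, which fell from 937 ± 298 to 171 ± 34.1 (-2.31, adjusted p = 0.0466). With the replicate number as a block, the latter was no longer called (adjusted p = 0.0553) and another probe set with no symbol, at 22.4 ± 18.8 in w1118 and 448 ± 208 in Wwox1, was gained (3.63, adjusted p = 0.0630 without the block and 0.00577 with it). At an unadjusted p under 0.05 limma gave 681 probe sets without the block and 1203 with it, where 938 are expected by chance. The CG14111 call was lost without Wwox1 replicate 1 (adjusted p = 0.0585), 2 (0.113) or 3 (0.122) or w1118 replicate 2 (0.110), and that of the probe set with no symbol without any array but w1118 replicate 1 (0.0549 to 0.362). CG7296 was called without any single array and lost where only the 2 groups compared were fitted (0.0525); its fold change was -3.79 with a pseudocount of 1 and -1.02 with 64. The count was 1 without any Wwox1 array or w1118 replicate 2, 2 without w1118 replicate 3 and 15 without w1118 replicate 1.

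Of the 27 gene lists, 2 were called in Wwox1, both lower. Mitochondrial ribosomal proteins were lower in 57 of 69 genes (median log2 fold change -0.18, adjusted p = 0.00161 with the preset and 0.969 with an estimated correlation, camera). By limma 0 members were called singly, with 2 lower at an unadjusted p under 0.05. The member with the smallest p was mRpL18 (-0.34, adjusted p = 0.998). Chorion and yolk genes of the ovary were lower in 10 of 13 (median -0.31, adjusted p = 0.0479, and 0.969 with an estimated correlation), the smallest p being that of Cp15, a chorion protein, at 59.6 ± 25.5 in w1118 and 12.9 ± 3.78 in Wwox1 (-1.34, adjusted p = 0.998). Against the w1118 pool of the same number, the medians for the numbers 1, 2 and 3 were -0.05, 0.02 and -0.44 for the mitochondrial list and -0.04, -0.98 and 0.03 for the chorion and yolk list. Without w1118 replicate 2 the chorion and yolk median was 0.01 (adjusted p = 0.819), and the call was also lost without Wwoxf04545 replicate 1 (0.0577), Wwox1 replicates 1 (0.0509), 2 (0.127) or 3 (0.128) and under quantile normalization. The mitochondrial call was lost without Wwox1 replicates 1 (0.672) or 3 (0.0798) and w1118 replicates 2 (0.248) or 3 (0.644). With the replicate block, oxidative phosphorylation (47 of 65 genes lower, adjusted p = 0.136 without and 0.0294 with the block) and digestive enzymes of feeding stages (21 of 28 lower, 0.136 and 0.00544) were called as well, at an adjusted p = 0.936 with an estimated correlation.

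Other metabolic lists and the stress lists were not called in Wwox1. The median was 0.09 over 18 genes of the TCA cycle and pyruvate dehydrogenase (adjusted p = 0.550), -0.12 over 18 genes of glycolysis and sugar metabolism (0.348) and 0.01 over 22 antioxidant and redox genes (0.972). Among 35 glutathione S-transferases, GstE1 alone was called when adjusted over the list alone, at 210 ± 74.8 in w1118 and 64.5 ± 19.2 in Wwox1 (log2 fold change -1.45, list-alone adjusted p = 0.00983, adjusted p = 0.469 over all probe sets). Heat shock proteins and chaperones (0.972), DNA damage and apoptosis genes (0.789) and antimicrobial and immune genes (0.993) were not called either. Without the block the 25 uncalled lists ran from an adjusted p of 0.136 to 0.993.

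In the insertion allele, 12 probe sets were called against w1118, 5 higher and 7 lower. A pseudocount of 1 left 1 call, Wwox, and array weights gave 581, 326 higher and the rest lower. Among the 12 were 3 cytochrome P450 genes. Cyp6g1, whose overexpression confers DDT resistance, fell from 103 ± 19.6 to 4.52 ± 3.42 (log2 fold change -2.54, SE 0.16, adjusted p = 0.000455). Cyp4p2 rose from 8.62 ± 6.59 to 109 ± 11.7 (2.37, SE 0.20, adjusted p = 0.00182) and Cyp4p1 from 8.42 ± 1.94 to 35.3 ± 6.42 (1.07, adjusted p = 0.0322). CG18088 rose from 23.5 ± 6.00 to 169 ± 35.4 (2.22, adjusted p = 0.00182), CG5973 from 36.2 ± 9.03 to 128 ± 7.25 (1.47, adjusted p = 0.00542) and CG14111 from 103 ± 18.0 to 234 ± 21.6 (1.09, adjusted p = 0.0448). The fold changes of dim signals depended on the pseudocount. With 1 and 64 they were -4.47 and -1.28 for Cyp6g1 (adjusted p = 1.04e-05 to 0.0775 over all settings) and 3.72 and 1.25 for Cyp4p2 (1.51e-05 to 0.315).

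Besides Cyp6g1 and Wwox, 5 probe sets fell in Wwoxf04545. CG15128 went from 52.7 ± 6.28 to 3.47 ± 2.74 (-1.82, adjusted p = 0.00166). Lkr, the receptor of the neuropeptide leucokinin, went from 18.7 ± 4.10 to 2.26 ± 1.20 (-0.92, adjusted p = 0.0431) and CG11597 from 56.5 ± 4.44 to 23.3 ± 2.49 (-0.88, adjusted p = 0.0324). With pseudocounts of 1 and 64 the fold change was -3.81 and -0.79 for CG15128 (adjusted p = 2.45e-05 to 0.140 over all settings) and -2.66 and -0.32 for Lkr (0.00105 to 0.373). A probe set with no symbol fell by 2.18 from 2100 ± 29.7 to 458 ± 107 (adjusted p = 0.00182), and one that matches both CG30059 and CG18278 fell by 1.52 (adjusted p = 0.0397). The replicate block left 8 of the 12 calls and ended those of CG14111 (adjusted p = 0.0582), Cyp4p1 (0.0577), CG11597 (0.0577) and the CG30059 and CG18278 probe set (0.0546). At an unadjusted p under 0.05 limma gave 924 probe sets without the block and 1562 with it, with 938 expected by chance, and quantile normalization gave 14 calls, 8 higher and 6 lower.

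Wwox, Cyp6g1, Cyp4p2, CG18088, CG15128 and the bright probe set with no symbol were called in Wwoxf04545 whichever single array was left out. CG5973 was lost without Wwoxf04545 replicates 2 or 3 or w1118 replicate 2 (adjusted p = 0.0534 to 0.0615) and Cyp4p1 without any array but Wwoxf04545 replicate 1 and w1118 replicate 1 (0.0690 to 0.209). CG11597 (0.0620 to 0.227) and Lkr (0.0892 to 0.240) were lost without any array but w1118 replicate 1, the CG30059 and CG18278 probe set without any but Wwoxf04545 replicate 1 (0.0631 to 0.240), and CG14111 without any of the 9 (0.0545 to 0.281). The count was 6 without Wwoxf04545 replicates 2 or 3 or w1118 replicate 2, 7 without any Wwox1 array or w1118 replicate 3, and 29 without w1118 replicate 1.

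The P450 list as a whole was not shifted in Wwoxf04545 (81 genes, 36 higher and 45 lower, median -0.01, adjusted p = 0.938). It held 3 called members, and 4 higher and 3 lower when adjusted over the list alone. Among 22 antioxidant genes the peroxiredoxin Prx6c passed over the list alone, at 63.2 ± 22.4 in w1118 and 253 ± 129 in Wwoxf04545 (1.70, list-alone adjusted p = 0.0149, adjusted p = 0.353 over all probe sets), and the list was not called (median -0.01, adjusted p = 0.935). The TCA cycle list had a median of 0.00 (adjusted p = 0.967) and the glutathione S-transferases one of -0.10 (0.914).

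With the preset correlation 5 lists were higher in Wwoxf04545 than in w1118. They were haemocyte and basement membrane genes (10 of 14 genes, median 0.31, adjusted p = 0.00650), mesoderm and muscle genes (10 of 12, 0.18, 0.00650), neural genes (14 of 17, 0.13, 0.00650), epidermal, tracheal and amnioserosa genes (13 of 17, 0.19, 0.00808) and JNK, AP-1 and EGFR signalling genes (12 of 14, 0.14, 0.0366). With an estimated correlation the adjusted p was 0.627 for the first 4 and 0.486 for the signalling list. No member was called singly over all probe sets. Over the list alone lmd, a myoblast transcription factor, was called at 350 ± 70.0 and 548 ± 38.1 (0.64, list-alone adjusted p = 0.0175), as was nau, the fly MyoD (0.44, 0.0195). LanA, a laminin chain, had the smallest p of the haemocyte list (0.51, SE 0.20, list-alone adjusted p = 0.202).

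With the preset correlation 6 lists were lower in Wwoxf04545, namely mitochondrial ribosomal proteins (59 of 69 genes, median -0.15, adjusted p = 0.00650), glycolysis and sugar metabolism (14 of 18, -0.25, 0.0103), oxidative phosphorylation (48 of 65, -0.11, 0.0421), cytosolic ribosomal proteins (32 of 34, -0.16, 0.0421), digestive enzymes of feeding stages (22 of 28, -0.20, 0.0421) and late embryonic cuticle genes (78 of 109, -0.09, 0.0421). With an estimated correlation the adjusted p was 0.938, 0.486, 0.938, 0.964, 0.891 and 0.876 in the same order. In glycolysis 3 genes were lower at an unadjusted p under 0.05 and 0 were called by limma, Pgm1 having the smallest p (-0.46, adjusted p = 0.883). The replicate block ended the cuticle call (adjusted p = 0.0545). Under quantile normalization the calls of oxidative phosphorylation (adjusted p = 0.122), digestive enzymes (0.104), cuticle genes (0.114) and cytosolic ribosomal proteins (median -0.00, 0.860) were lost.

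The haemocyte list was called in Wwoxf04545 whichever single array was left out. The neural call was lost without w1118 replicates 2 (adjusted p = 0.0622) or 3 (0.0581), the mesoderm and muscle call without Wwoxf04545 replicate 2 (0.0501) or w1118 replicate 3 (0.131), the epidermal call without Wwoxf04545 replicate 2 (0.125) or w1118 replicate 2 (0.0619), and the glycolysis call without Wwoxf04545 replicate 1 (0.0658) or w1118 replicate 2 (0.0681). The signalling call was lost without Wwoxf04545 replicates 2 or 3 or w1118 replicates 2 or 3 (0.0613 to 0.132), and mitochondrial ribosomal proteins without Wwoxf04545 replicate 1 or w1118 replicates 2 or 3 (0.163 to 0.800). Oxidative phosphorylation was lost without Wwoxf04545 replicates 1 or 2 or w1118 replicates 2 or 3 (0.0501 to 0.800), and cuticle genes without Wwoxf04545 replicates 1 or 3 or w1118 replicates 1 or 2 (0.130 to 0.407). Cytosolic ribosomal proteins were lost without Wwoxf04545 replicates 2 or 3, Wwox1 replicate 2 or w1118 replicate 3, and had a median of 0.06 without w1118 replicate 1 (0.0558 to 0.951). Digestive enzymes were lost without any array but Wwoxf04545 replicate 3, Wwox1 replicate 3 and w1118 replicate 2 (0.0532 to 0.728).

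The tissue lists differed between replicate numbers. Against the w1118 pool of the same number, the median of the haemocyte list was -0.21, 0.43 and 0.54 in Wwoxf04545 for the numbers 1, 2 and 3. That of the mesoderm and muscle list was -0.12, 0.38 and 0.40, that of the neural list -0.17, 0.32 and 0.32, and that of the epidermal list -0.10, 0.46 and 0.22. Maternal transcripts went the other way, at 0.50, -0.53 and -0.23, as did germ cell markers at 0.22, -0.30 and -0.29. Neither list was called over the 3 pools (medians 0.06 and -0.06, adjusted p = 0.938 each). Mitochondrial ribosomal proteins were at 0.02, -0.19 and -0.28, and cytosolic ones at -0.13, -0.11 and -0.27. Glycolysis was at -0.35, -0.27 and -0.12, oxidative phosphorylation at -0.04, -0.15 and -0.19, and the signalling list at 0.02, 0.14 and 0.25. Digestive enzymes were at -0.48, -0.20 and -0.01, and cuticle genes at -0.17, -0.05 and 0.02.

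**Figure D2:**
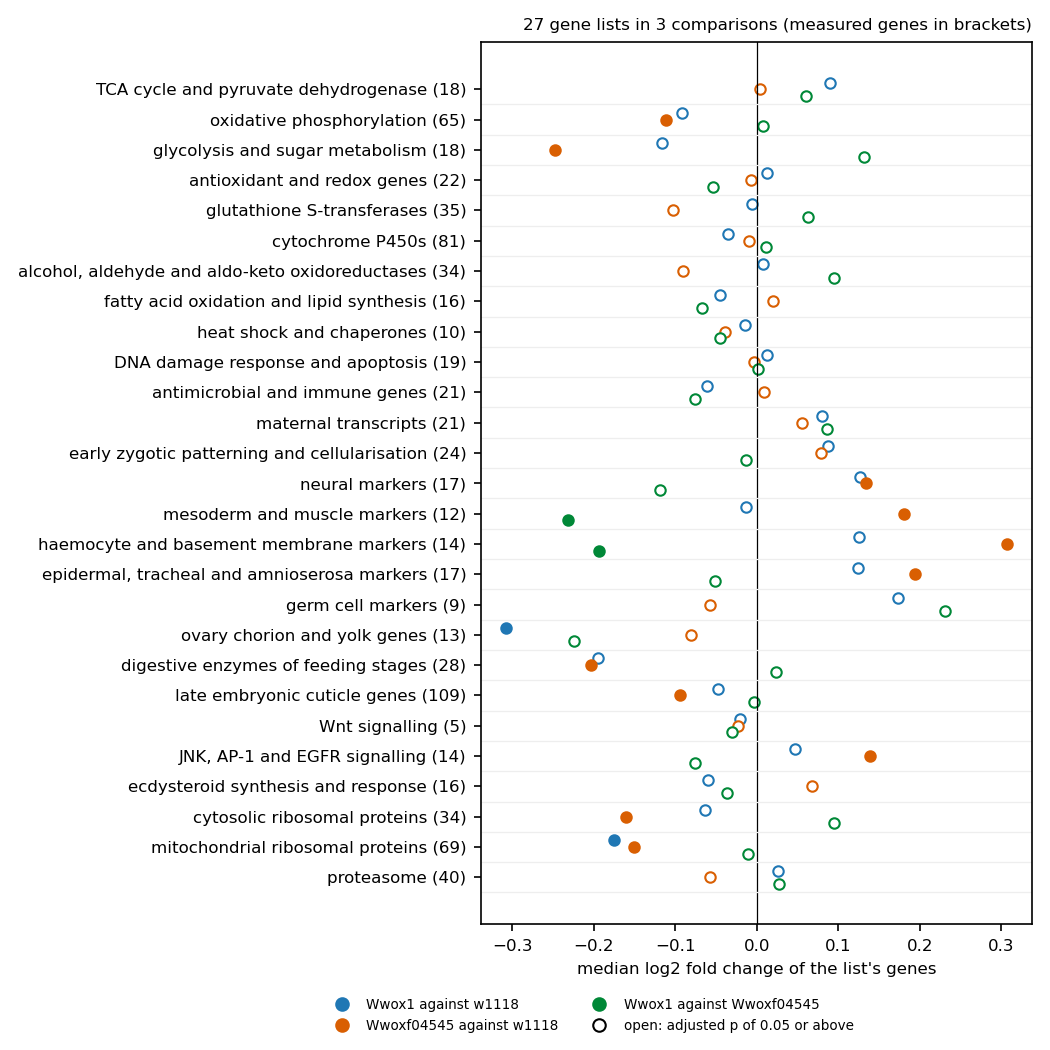
Median log2 fold change of the measured genes of each of the 27 lists in the 3 comparisons; filled points have an adjusted p under 0.05 with the preset correlation and open points do not. In Wwoxf04545 against w1118, 5 lists lay above and 6 below, in Wwox1 against w1118 2 lay below, and between the mutants 2 did; none of these had an adjusted p under 0.05 with an estimated correlation (0.486 to 0.969).

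**Figure D3:**
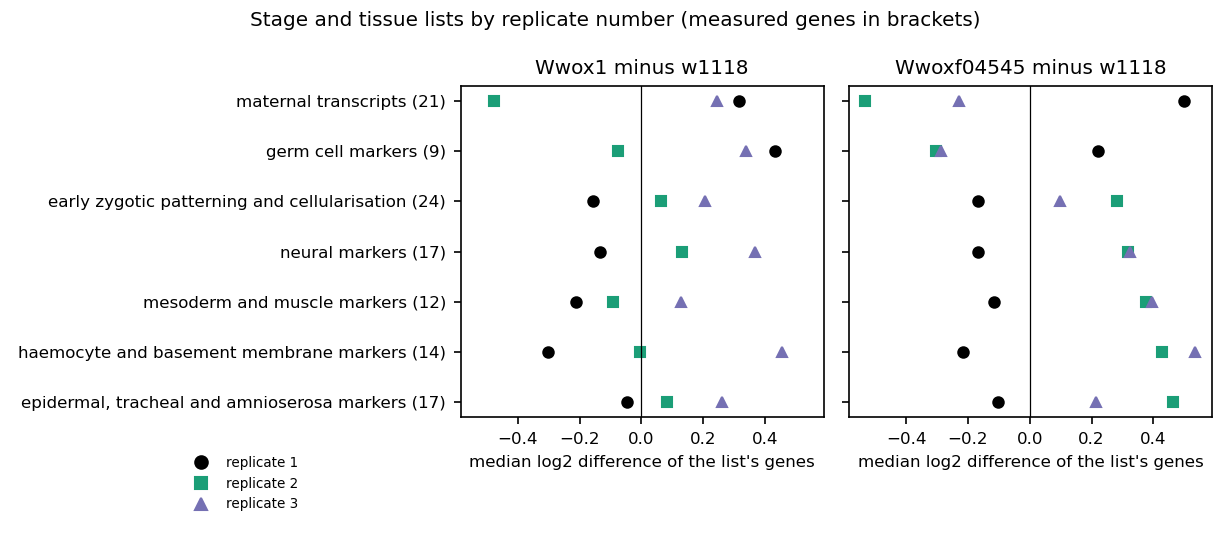
Median log2 difference of 7 stage and tissue lists between each mutant pool and the w1118 pool of the same replicate number, 1 symbol per number. In Wwoxf04545 the 4 tissue lists lay below 0 in number 1 and above 0 in numbers 2 and 3, and maternal transcripts the reverse.

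Between the mutant stocks, 12 probe sets were called, 6 higher in Wwox1 and 6 higher in Wwoxf04545. The P450 list was not called (81 genes, median 0.01, adjusted p = 0.291, and 0.882 with an estimated correlation). Its called members were 3, with Cyp6g1 at 111 ± 4.63 in Wwox1 and 4.52 ± 3.42 in Wwoxf04545 (log2 fold change 2.64, adjusted p = 0.000635), Cyp4p2 at 3.61 ± 3.26 and 109 ± 11.7 (-2.68, adjusted p = 0.00186) and Cyp4p1 at 5.09 ± 1.35 and 35.3 ± 6.42 (-1.28, adjusted p = 0.00710). The gene poe, which encodes a calmodulin-binding UBR4-type protein, was at 1237 ± 313 in Wwox1 and 220 ± 10.2 in Wwoxf04545 (2.38, adjusted p = 0.0466), and CG14275 at 53.6 ± 11.4 and 5.56 ± 4.44 (1.70, adjusted p = 0.0163). CG15128 was higher in Wwox1 (1.69, adjusted p = 0.00243). Spn55B, a serine protease inhibitor, was lower at 115 ± 10.2 against 223 ± 14.8 (-0.86, adjusted p = 0.0482).

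CG18088 (-2.34, adjusted p = 0.00214), CG5973 (-1.45, adjusted p = 0.00654) and CG7296 (-1.48, adjusted p = 0.00654) were also lower in Wwox1 than in Wwoxf04545. Probe sets with no symbol were higher at 448 ± 208 against 8.45 ± 3.83 (4.13, adjusted p = 0.0153) and at 1948 ± 308 against 458 ± 107 (2.07, adjusted p = 0.00349). At an unadjusted p under 0.05 limma gave 622 probe sets without the block and 899 with it, with 938 expected by chance. The replicate block kept all 12 and gave 16 calls, adding CG9171 (adjusted p = 0.206 without and 0.0263 with the block), Acbp1 (0.629 and 0.0145), CG11327 (1 and 0.0375) and a probe set with no symbol (0.141 and 0.0487). The count of calls between the mutants fell to 5 without Wwox1 replicate 3, Wwoxf04545 replicate 2 or Wwoxf04545 replicate 3 and to 7 without Wwox1 replicate 2, and rose to 21 without w1118 replicate 1, which enters through the shared variance. Without single arrays the calls of poe (adjusted p = 0.0569 to 0.324) and Spn55B (0.110 to 0.386) were lost for any array but w1118 replicate 1, and that of CG14275 for any Wwox1 array and Wwoxf04545 replicates 2 and 3 (0.0571 to 0.123). Those of CG5973 (0.0571 to 0.0686) and CG7296 (0.0555 to 0.0617) were lost without Wwox1 replicate 3 or Wwoxf04545 replicates 2 or 3, and that of Cyp4p1 without these or Wwox1 replicate 2 (0.0571 to 0.0789). The first probe set with no symbol was lost without any Wwoxf04545 array or Wwox1 replicates 2 or 3 (0.0789 to 0.116).

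**Figure D4:**
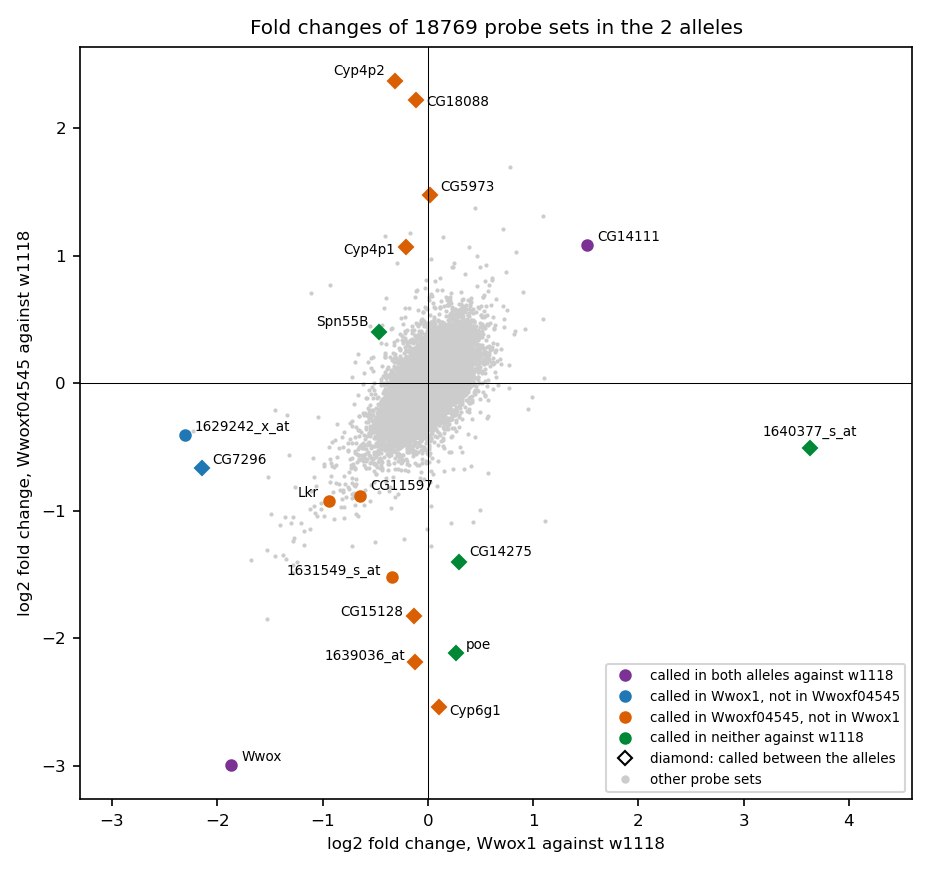
Log2 fold change of each of 18769 probe sets in Wwox1 (x axis) and Wwoxf04545 (y axis) against w1118; coloured points are called in at least 1 comparison and diamonds between the mutants. Wwox and CG14111 are called in both mutants; Cyp6g1, poe, CG15128, CG18088, CG5973, Cyp4p1 and Cyp4p2 lie along the Wwoxf04545 axis.

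Mesoderm and muscle genes were lower in Wwox1 than in Wwoxf04545 in 12 of 12 genes (median log2 fold change -0.23, adjusted p = 0.000233, camera), and haemocyte and basement membrane genes in 14 of 14 (-0.19, adjusted p = 0.00198). With an estimated correlation the adjusted p was 0.631 for both. The members with the smallest p were lmd (-0.44) and Pxn, peroxidasin (-0.54), each at an adjusted p of 1 over all probe sets. Without Wwox1 replicate 2 the haemocyte call was lost (median -0.12, adjusted p = 0.324). The replicate block added the chorion and yolk genes (11 of 13 lower, adjusted p = 0.0965 without and 0.0175 with the block) and the cytosolic ribosomal proteins (32 of 34 higher, 0.126 and 0.00859), at an adjusted p = 0.815 and 0.879 with an estimated correlation. The 25 uncalled lists ran from an adjusted p of 0.0965 to 0.956.

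Calls in the same direction in both alleles against w1118 were 2, Wwox lower and CG14111 higher. The count was 0 without any Wwox1 array or w1118 replicates 2 or 3, 1 without any Wwoxf04545 array, 8 without w1118 replicate 1 and 17 with array weights. Lists of calls that were independent of each other would share 0.00112 lower and 0.000266 higher. These lists use the same w1118 arrays and both hold the altered gene, so those are not chance values for them. Simulated unchanged groups against 1 simulated w1118 group shared 0. With independent noise and no group difference that count is close to fixed in advance, so nothing is drawn from it. Lkr came close in Wwox1 (2.04 ± 0.841, log2 fold change -0.94, adjusted p = 0.0630). Across probe sets, which are not independent replicates, the fold changes of the alleles correlated at r = 0.597, and simulated unchanged groups against shared controls gave r = 0.502. The covariance was 0.0267 against 0.0235 simulated with the spread of the unblocked model and 0.0154 with that of the blocked one. With 3 controls, each allele cannot be given its own replicated controls, so part of any excess may come from the shared arrays. With the replicate block, Wwox was the 1 shared call.

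Genes in the neighbourhood of Wwox were compared with the rest of the genome because an allele is kept together with its flanking chromosome. In Wwoxf04545 against w1118, 2 of 221 measured genes within 1 Mb of Wwox were called, CG18088 and CG5973 (0.905%), and 7 of 11672 elsewhere (0.0600%; Fisher's exact test, two-sided, p = 0.0114). Between the mutants 4 of 221 were called, CG14275, CG18088, CG5973 and poe (1.81%), against 6 of 11672 (0.0514%; Fisher's exact test, p = 2.23e-05). In Wwox1 against w1118 the counts were 0 of 221 and 2 of 11672 (Fisher's exact test, p = 1), and with a window of 5 Mb 1 of 1091, CG7296, and 1 of 10802 (Fisher's exact p = 0.175). With a window of 0.25 Mb Wwox1 had 0 of 67 (Fisher's exact p = 1), Wwoxf04545 against w1118 had 0 of 67 and the mutants 1 of 67, poe (Fisher's exact p = 1 and 0.0549), and with 5 Mb the last 2 had 2 and 5 of 1091 (Fisher's exact p = 0.197 and 0.00109). Within 1 Mb, Wwoxf04545 against w1118 and the mutants had 1 of 221 each (Fisher's exact p = 0.0723) without Wwoxf04545 replicate 2 or replicate 3, the former also without w1118 replicate 2 and the latter without Wwox1 replicate 3.

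**Figure D5:**
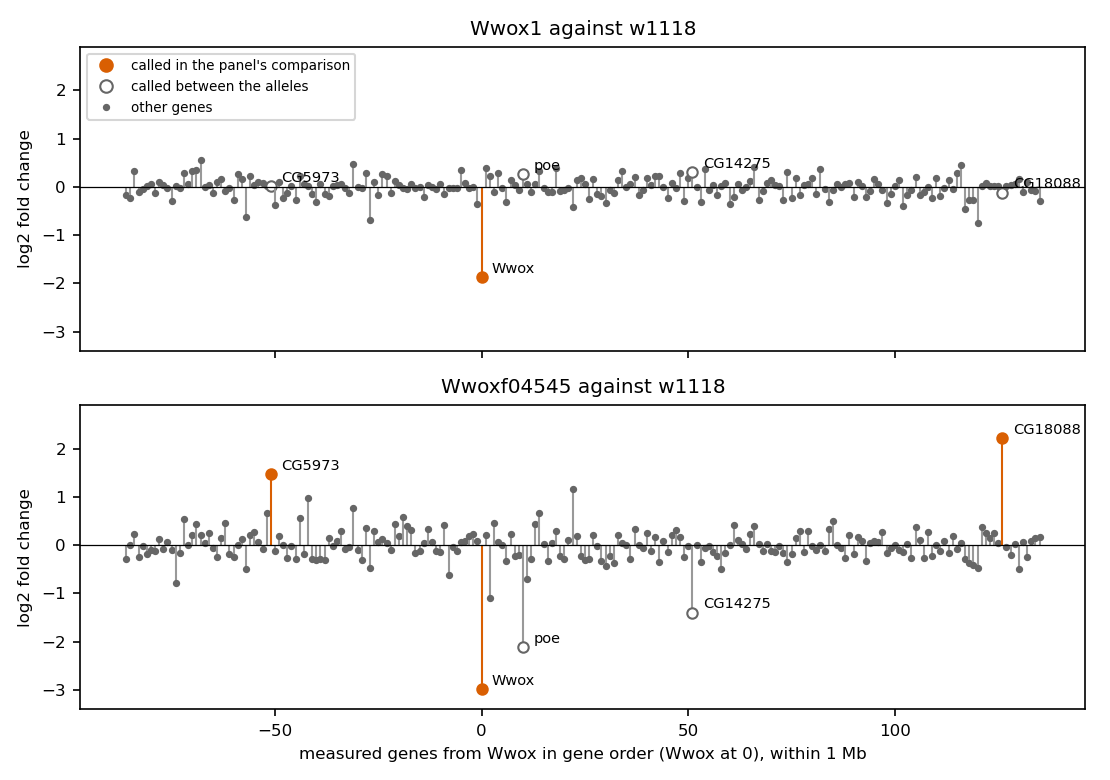
Log2 fold change against w1118 of the measured genes within 1 Mb of Wwox, in gene order with Wwox at 0, in Wwox1 (top) and Wwoxf04545 (bottom); filled coloured points are called in the panel's comparison and open points between the mutants. CG5973 lies 51 measured genes to one side, and poe, CG14275 and CG18088 lie 10, 51 and 126 to the other.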

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

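The tests on ribosomal RNA, on a loss of function shared by both alleles, on chromosome 2, on correlation within lists, on embryo age and on shared calls besides Wwox were chosen after the results were seen; the others were chosen before.

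The 2 mutant stocks differed, by the test of the difference itself, for 12 probe sets, given as the log2 fold change of Wwox1 against Wwoxf04545. The values were 4.13 for a probe set with no gene symbol, 2.64 for Cyp6g1, 2.38 for poe, 2.07 for another with none, 1.70 for CG14275 and 1.69 for CG15128. They were -0.86 for Spn55B, -1.28 for Cyp4p1, -1.45 for CG5973, -1.48 for CG7296, -2.34 for CG18088 and -2.68 for Cyp4p2. No test for a single outlying array was run within the groups of 3. Array weights from limma were 0.229 to 0.387 for the arrays numbered 1 and 0.702 to 2.56 for the others. Among the 183 control probe sets 0 were called by limma in any comparison, with 10, 8 and 7 at an unadjusted p under 0.05.

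Cyp6g1, CG15128, Cyp4p1, Cyp4p2, CG18088, CG5973 and the second of these probe sets with no symbol were called in Wwoxf04545 against both w1118 and Wwox1. A loss of Wwox function common to both alleles would not separate them, yet 7 of the 11 calls besides Wwox were also called between the mutants. The 11 were selected on the same Wwoxf04545 arrays that enter the second comparison, which raises this share. The share itself is therefore not a test, while each call between the mutants was adjusted over all probe sets. A chromosome segment carried with the allele may account for genes near Wwox (Fisher's exact p = 0.0114). With all other genes as background, that test cannot part such a segment from a difference over all of chromosome 2. Moreover, 7 called genes lay outside a 5 Mb window around Wwox. A candidate explanation for part of these is second chromosomes that differ between the stocks: of 27 probe sets under an unadjusted p of 0.001 between the mutants that were not called, Wwox left out, 24 lay on chromosome 2, against 5160 of 13506 others (Fisher's exact p = 7.18e-08). It leaves 3 of the 9 called genes, CG14111, Lkr and CG11597, since 6 lay on chromosome 2 (Fisher's exact p = 0.0939). These 3 moved the same way in Wwox1 (1.51, -0.94 and -0.65), against the same w1118 arrays, and were not called between the mutants. A shared loss of Wwox function stays open for them, but so does any other difference of the w1118 stock from both mutant stocks. With a single control stock these cannot be told apart. Between the mutants, 10 of 10 called genes with a known arm lay on chromosome 2. Whether some calls respond to the insertion itself stays open, and an effect of Wwox that differs between the alleles was not tested. Probe sequences were not available here, so whether the probes bind alike in all stocks was not tested either.

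The 3 arrays numbered 1 stood apart in every genotype. A 3' bias of degraded RNA would raise the 3'/5' ratio of actin and GAPDH, whose mean log2 ratio differed by -0.39, through actin (1.61 to 1.84 there, 2.21 to 3.09 elsewhere): GAPDH overlapped (2.02 to 3.05 and 2.46 to 3.01), and the ratio of 18S rRNA was higher there (1.25 to 2.13 against 0.18 to 0.60), so a bias in the ribosomal RNA stays open. Scaling by 1 factor per array would vanish under quantile normalization, and the mean correlation of the 3 arrays' deviations was still 0.402. A different spread of embryo stages could be neither shown nor excluded. Shifts were taken as the median over a list's genes of the mean over genotypes. The maternal list shifted by 0.0014, at -0.54 in w1118, 0.01 in Wwox1 and 0.28 in Wwoxf04545. The neural, mesoderm and haemocyte lists shifted by 0.10, 0.15 and 0.13, and all probe sets by 0.08. By genotype these 3 lists were at 0.37, 0.51 and 0.51 in w1118, 0.08, 0.20 and 0.16 in Wwox1 and -0.06, -0.03 and -0.24 in Wwoxf04545. After quantile normalization the maternal list was at -0.13, these 3 at 0.13, 0.15 and 0.07, and all probe sets at 0.01. More ribosomal RNA in the labelled target may be involved, since the 3' and 5' probe sets of 18S rRNA were at 295 to 1136 and 92.9 to 457 there and at 29.1 to 68.0 and 23.7 to 57.9 elsewhere, but the middle probe set overlapped, its lowest value being 0.987 of the highest elsewhere.

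The tissue lists higher in Wwoxf04545 were the third pattern. Correlation between the genes of a list stays open as a source of the calls. With an estimated correlation the adjusted p of the 4 tissue lists was 0.627 (camera). That version called 0 lists in any comparison, with a lowest adjusted p of 0.486, and was not tried on simulated data. Its lack of calls therefore does not show that correlation is the source. All 4 tissue lists lay below 0 in replicate number 1, down to -0.21, so the shift came from numbers 2 and 3. Older embryos in all Wwoxf04545 pools would lower the early zygotic list, and this stays open: its median was 0.0792 (adjusted p = 0.0800, and 0.811 with an estimated correlation), at -0.17, 0.28 and 0.10 by replicate number. Embryo pools that differ in age whatever the genotype can be neither shown nor excluded: by replicate number the maternal and mean tissue medians were 0.50 and -0.15, -0.53 and 0.40, and -0.23 and 0.37 in Wwoxf04545 and 0.31 and -0.17, -0.48 and 0.03, and 0.24 and 0.30 in Wwox1, in opposite directions in 5 of 6 pools. Both mutants of a number share 1 w1118 pool, so the 6 are not independent. The w1118 pools also differed among themselves in such lists, as given above. Number 1 against numbers 2 and 3 was at -0.54 for the maternal list in w1118 and 0.28 in Wwoxf04545. For the neural, mesoderm and haemocyte lists it was at 0.37, 0.51 and 0.51 in w1118, and -0.06, -0.03 and -0.24 in Wwoxf04545. For these lists the change of sign between numbers thus came in larger part from the w1118 pools.

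Other splits of the arrays were counted. For each comparison 10 splits of 6 arrays exist, too few for a share under 0.05. Wwox1 against w1118 had 4 calls and the highest other split 488, that of Wwox1 replicates 1 and 3 with w1118 replicate 1 against the rest, which parts only 1 replicate pair and points to a structure of the pools; the real split and 1 other, 2 in all, had as many calls. Wwoxf04545 against w1118 had 12 and the highest other 0, so 1 split in all. Between the mutants the count was 12 and the highest other 41, for Wwox1 replicates 1 and 3 with Wwoxf04545 replicate 1, again 2 in all. Among the 4 splits that part all 3 pairs, no other split gave a call in any comparison, with or without the replicate block, where the real counts were 4, 8 and 16. For the lists the real counts were 2, 11 and 2 and the highest others 10, 11 and 6, with 10, 2 and 10 of the 10 splits as high. Of 100 splits of the 9 arrays, the real one included, 2 shared as many calls between the alleles, with 3 the highest other. Wwox is the altered gene, and with it left out the real count was 1, CG14111. Of 100 splits that keep the replicate numbers, the real one included, 6 had as many, with 7 the highest other. Such splits can make all arrays of a mutant stock the shared reference, so real differences between the stocks can also give shared calls. They cannot tell how often chance gives as many, so chance was not excluded for CG14111. With the replicate block the count besides Wwox was 0 by limma (1203 and 1562 probe sets at an unadjusted p under 0.05). The CG14111 call in Wwoxf04545 was lost without any 1 of the 9 arrays (adjusted p = 0.0545 to 0.281) and with the replicate block (0.0582). For the agreement of fold changes chance was not excluded either, since 30 of the first 100 splits, the real one included, gave a correlation as high as 0.597, up to 0.765. Those splits ignore the replicate numbers, which were taken to pair the pools, and the correlation was not tested on splits that keep them.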

How the results depend on the processing

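Leaving out the 3 arrays numbered 1 together, and quantile normalization with the replicate block, were chosen after the data were seen. Of the values of 127 results under the 27 settings, 2633 kept direction and side of the threshold, 267 lost a call, 28 gained one and 4 reversed. For lists the direction was that given by camera. The 127 results include list members that were never called and so had no call to lose. Of the 28 calls over the 3 comparisons, Wwox included, 4 were kept with a pseudocount of 1, 13 without Wwox1 replicate 3 and 28 with array weights. The Wwox call in Wwoxf04545 held in 23 of 23 settings and that of CG18088 between the mutants in 23 of 23. In the order Wwox1 against w1118, Wwoxf04545 against w1118 and Wwox1 against Wwoxf04545, a pseudocount of 1 gave 1, 1 and 3 calls and array weights 21, 581 and 74. For the first comparison a pseudocount of 64 gave 2. For the first and second, limma on only the 2 groups compared gave 0 (580 at an unadjusted p under 0.05) and 6, an adjusted p under 0.01 gave 1 and 7, and leaving out the arrays numbered 1 gave 10 and 28. Calls shared by both alleles numbered 1 with the replicate block, with median centring and with quantile normalization plus block, 0 with either pseudocount, with only the 2 groups compared and at an adjusted p under 0.01, 17 with array weights and 4 without the arrays numbered 1. Median centring gave 2 higher and 3 lower in Wwox1.

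Called lists in the same order were 4, 10 and 4 with the replicate block and 0, 0 and 0 with an estimated correlation. For the first and second they were 1 and 7 with quantile normalization, 1 and 6 with a pseudocount of 1, and 1 and 5 at an adjusted p under 0.01. For the first they were 1 with a pseudocount of 64, 6 without the arrays numbered 1 and 4 with quantile normalization plus block, and array weights gave 6 for the first and 4 for the last. Genes near Wwox called in Wwoxf04545 were 0% with a pseudocount of 1 and in a 0.25 Mb window, 0.452% with only the 2 groups compared, 0.183% in a 5 Mb window and 0.905% (Fisher's exact p = 0.0674) without the arrays numbered 1. Between the mutants they were 1.49% in a 0.25 Mb window. Wwox in Wwox1 was at -2.45 (adjusted p = 0.214) with a pseudocount of 1, -1.11 (0.110) with 64, -1.87 (0.228) with only the 2 groups compared, and -1.87 (0.0111) missed an adjusted p under 0.01, against 0.000173 to 0.228 over all settings. The reversed values were 0.0136 for the chorion and yolk list in Wwox1 without w1118 replicate 2 (down to -0.493 without w1118 replicate 1), -0.0274 for RpL10Aa in Wwox1 without Wwox1 replicate 1 (up to 0.409 without replicate 3), and, for Axn between the mutants, 0.0305 with array weights and 0.0899 without Wwox1 replicate 2 (down to -0.252 without replicate 3). RpL10Aa and Axn were not called. The median of the cytosolic ribosomal list in Wwoxf04545 also changed sign, from -0.16 to 0.0642 without w1118 replicate 1 (adjusted p = 0.951, camera). It was not counted as reversed, since its direction by camera did not turn.

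Leaving out 1 array at a time gave 1 to 15, 6 to 29 and 5 to 21 calls, 0 to 8 shared calls, a fold change correlation of 0.447 (without Wwoxf04545 replicate 1) to 0.733 (without w1118 replicate 1), and 1 to 6, 4 to 11 and 2 to 6 called lists. The highest call counts all came without w1118 replicate 1. Genes near Wwox ranged from 0.452% to 1.36% in Wwoxf04545 and to 2.26% between the mutants, Wwox from -2.08 to -1.73 in Wwox1 and -3.21 to -2.86 in Wwoxf04545. The replicate block changed no call beyond those given with its value. Fewer arrays or groups leave fewer degrees of freedom; otherwise the cause was not tested. What the signal over background limits was not tested beyond the pseudocounts and the filter on dim probe sets.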

Other observations

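All tests and genes in this part were chosen after their values were seen.

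Several genes had like values in both alleles without passing the threshold in both. Arpc1, a subunit of the Arp2/3 actin nucleator, was at 312 in w1118, 111 in Wwox1 and 110 in Wwoxf04545 (log2 fold change -1.34 and -1.37, adjusted p = 0.356 and 0.126). CG5773 was at 130, 46.6 and 40.4 (-1.25 and -1.40, adjusted p = 0.469 and 0.126). CG11597 fell by 0.88 in Wwoxf04545 and was at -0.65 in Wwox1 (adjusted p = 0.365), and Lkr was at -0.94 and -0.92. None of these differed between the mutants (adjusted p = 1 for each), which does not show that they were equal. Without the 3 arrays numbered 1, 4 probe sets were called in the same direction in both alleles: Wwox, Tektin-C (-1.65 and -1.82), the antisense RNA asRNA:Eig63F-2 (-1.86 and -1.79) and Pepck2, a phosphoenolpyruvate carboxykinase (1.41 in Wwox1, adjusted p = 0.0334, and 1.79 in Wwoxf04545, adjusted p = 0.0112). CG14111 was not among them, and Tektin-C, asRNA:Eig63F-2 and Pepck2 were not called with all 9 arrays.

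Named probe sets that differed between Wwoxf04545 and w1118 below the threshold lay on the second chromosome. Of 27 named probe sets at an unadjusted p under 0.001 against w1118 that were not called, 27 lay on chromosome 2, 14 on arm 2L and 13 on 2R, where 38.2% of the other named probe sets lie (5161 of 13507, Fisher's exact p = 5.47e-12). They included Arpc1 and CG5773, given above with like values in Wwox1, as well as Cyp4d21 (0.97) and Prx6c (1.70), the kinetochore gene Nuf2 (-0.78), the small RNA methyltransferase Hen1 (-1.14) and poe (-2.11). In Wwox1 against w1118, 3 of 6 such probe sets lay on chromosome 2 (Fisher's exact p = 0.681). Lkr and CG11597, called in Wwoxf04545 and not in Wwox1, lay on arm 3L, as did CG14111, called in both. All 3 moved the same way in both alleles, against the same w1118 arrays.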
